A study of Homo sapiens with 4 samples.

How the data were processed

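Total RNA was extracted from Panc1 cells with TRI reagent, and biotin-labelled cRNA was made from 100 ng of it with a GeneChip 3′ IVT kit, per the labels' protocols. The 4 samples were untreated cells and cells treated for 24 hours with romidepsin, tamoxifen or both, with 1 array each. The deposited values are probe-set intensities on a linear scale made with MAS5, per the submitters' processing notes. Its version was not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array on its own. The mean of the deposited signals, after 2% of the values at each end were trimmed, was 500.1 on all 4 arrays, so that the scaling takes the bulk of the signal to be equal in all samples. Median signals were 59.7 for untreated cells, 68.0 for romidepsin, 66.1 for tamoxifen and 73.2 for the combination. Scanner files were not used here, so background correction, slide and scan date could not be varied.

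Each array holds 54675 probe sets, of which 62 are controls. The platform annotation names 1 gene for 41097 probe sets, several for 1801 and is silent for 11721; the last were not named here. Symbols were checked by Entrez ID against the RefSeq gene table of assembly GCF_000001405.40 (GRCh38.p14), which matched 41043 probe sets and changed 0 symbols. That table was used for names, gene length and chromosome only. Probe sets with 1 gene covered 19775 genes, and each gene was represented by its probe set with the highest mean log2 signal over the 4 arrays. Values below the median of all non-control signals, 66.4, were set to that floor before log2 was taken. Signals that low have no order, and a fold against a gene at the floor is a lower bound, written as at least N-fold. A gene was measured in a comparison if at least 1 of the 2 arrays lay above the floor. It was called where it differed by at least 2-fold. A gene at the floor on 1 of the 2 arrays can therefore differ in 1 direction only. Columns of other samples numbered 0.

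Samples were grouped by their labels. The comparisons were each drug and the combination against untreated cells, and the combination against each drug. With 1 array per group no test between groups was made, and folds describe these arrays only. The 38 gene lists, the rule for genes named, the comparisons and most alternatives were fixed before the data were examined. A list's median log2 fold was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean signal, and a list stands outside the central range below percentile 2.5 or above 97.5. Lists with fewer than 5 measured members got no percentile. Of 701 list genes, 77 had no probe set that names them alone in the annotation used and were not analysed here.

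Genes were named only if all their measured probe sets moved in 1 direction. For the single drugs these were the 8 largest rises and falls measured on both arrays and the 3 largest with the lower array at the floor. The romidepsin genes also had to change at least 2-fold the same way in the combination over tamoxifen, and the tamoxifen genes to have the same sign in the combination over romidepsin. For the combination against untreated cells they were the 8 and 3 largest, against each drug the 6 largest, and for genes set apart on the combination array the 6 with the largest margin each way. Of each list described, up to 4 members with the largest folds could be named, and a short set of genes fixed in advance was always reported.

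The spread that could be measured was technical only. The median absolute difference between the log2 folds of 2 probe sets of a gene lay between 0.22 and 0.29 in the 5 comparisons. The SD of log2 folds over the 18 hybridization spike-in probe sets lay between 0.09 and 0.11. Neither includes variation between cultures.

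Calculations were made in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. The steps were tested on simulated data in which 200 genes of the romidepsin comparison were changed, with noise of SD 0.18 on the log2 scale, among 12911 genes measured. Of 50 genes changed 1.5-fold 3 were called, of 50 changed 2.5-fold 45, of 50 changed 4-fold 43 and of 50 changed 8-fold 46. The misses were looked at after an earlier version of the test fell short of its pass mark. Of 75 simulated falls of 2.5-fold or more 14 were missed, and all 14 were genes within 2-fold of the floor, where a 2-fold fall cannot be seen; of 75 simulated rises 2 were missed. The pass mark of over 90% was then applied to genes that could be called, and the falls of dim genes are under-counted in the real data too. Of 12717 unchanged genes 1 was called. The simulated noise was equal for all genes and was estimated from probe sets above the floor. It leaves out variation between cultures and any larger noise of dim signals, so this rate does not carry over to the real arrays. Of 200 unchanged lists 8 lay outside the central range, and of 50 lists shifted by 0.5 all 50 were found.

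Alternatives were centring arrays on their medians, quantile normalization, a floor at the 25th or 75th percentile, a constant of 16 added in place of a floor, the median over a gene's probe sets, leaving out probe sets with IDs ending in _x_at or _s_at, and random lists not matched on signal. Scaling to the hybridization spike-in controls and removal of trends with gene length and chromosome were added after the data were seen.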

Results

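Gene expression was measured in Panc1 cells, a human pancreatic cancer cell line, on 4 Affymetrix arrays with 1 array per condition. The conditions were untreated cells and cells treated for 24 hours with romidepsin, with tamoxifen or with both drugs. Romidepsin inhibits histone deacetylases, the enzymes that remove acetyl groups from histones, and tamoxifen is a selective estrogen receptor modulator. The doses were not given in the sources used here. The design asks what each drug does alone, and what each adds to the other. There were no replicates, and no p-value is given. An additive model of both drugs would leave 1 residual degree of freedom, which holds any interaction of the drugs as well as noise, and it was not fitted. The number of arrays limits the precision of every value. A gene is said to rise or fall where its signal differed by at least 2-fold between 2 arrays.

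Signals lay above the floor of 66.4 for 12159 genes on the untreated array, 12988 on the romidepsin array, 12479 on the tamoxifen array and 13150 on the combination array. Across probe sets, the log2 signals of the romidepsin and combination arrays correlated at r = 0.93, and those of the untreated and tamoxifen arrays at r = 0.92. The untreated and combination arrays had the lowest correlation, r = 0.87. The 3′ to 5′ signal ratio of the actin control, a measure of RNA integrity, was 1.21 on the untreated array, 1.18 on the romidepsin array, 1.39 on the tamoxifen array and 1.73 on the combination array. The same ratio of the GAPDH control lay between 1.03 and 1.07. Hybridization spike-in controls were at 0.78 times the untreated level on the tamoxifen array and 0.82 times on the combination array, against 1.01 times on the romidepsin array. These controls carry no RNA of the cells.

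Romidepsin alone was compared with no treatment. Mitosis genes were lower in the treated cells, while histone genes, inhibitors of cyclin-dependent kinases and neuronal genes were higher. Of 29 measured mitosis genes and targets of the transcription factor FOXM1, 25 fell and 0 rose, with a median log2 fold of -1.51. FOXM1 itself had a signal of 2353 in untreated cells and 421 with romidepsin, 5.58-fold lower. CDKN1A, which encodes the cell cycle inhibitor p21, went from 1047 to 7755, 7.41-fold higher. In all, 1953 genes rose and 1263 fell among 13619 measured, so that 60.7% of the calls were rises; with arrays centred on their medians 1573 rose and 1743 fell, or 47.4% rises.

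The largest rise among genes measured on both arrays was that of DHRS2, a short-chain dehydrogenase, from 346 to 23549, 68.0-fold. ABAT, the enzyme that breaks down the neurotransmitter GABA, rose 43.9-fold, and GATM, an enzyme of creatine synthesis, rose 32.3-fold. GPR160 rose 29.8-fold, DNER 27.3-fold, PRKAR2B, a regulatory subunit of protein kinase A, 25.9-fold, cyclin D2 (CCND2) 25.3-fold and the homeobox gene ESX1 22.5-fold. The untreated signals of GATM, GPR160, DNER, PRKAR2B, CCND2 and ESX1 lay between 67.9 and 79.7, close to the floor, so these folds depend on it. Of genes at the floor in untreated cells, NLRP5 rose at least 39.8-fold, the nerve growth factor receptor NGFR at least 35.9-fold and ZCCHC12 at least 33.2-fold. The largest fall was that of PLAU, which encodes urokinase, from 9337 to 296, 31.6-fold lower. FOSL1, a subunit of the transcription factor AP-1, was 23.7-fold lower, MYOF (myoferlin) and the stress-response gene NUPR1 were each 18.7-fold lower, and DACT2 was 14.6-fold lower. The hyaluronan synthase HAS3 fell 13.1-fold, EMP1 12.7-fold and the transcription factor ETS2 11.5-fold. ASB4 was at least 11.1-fold lower, the noncoding RNA DLGAP1-AS2 at least 9.01-fold lower and the macrophage growth factor CSF1 at least 6.76-fold lower.

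Other cell cycle lists moved with the mitosis genes. Of 29 genes of DNA replication and the G1/S transition, 16 fell and 0 rose, with a median of -1.29. Examples were UHRF1, 5.81-fold lower, the thymidylate synthase gene TYMS, 5.47-fold lower, and the replicative helicase subunit MCM5, 4.44-fold lower. Of 14 genes of homologous recombination and the Fanconi pathway, 6 fell, with a median of -0.80, RAD54L 3.0-fold lower and RAD51AP1 2.53-fold lower. The medians of the mitosis and replication lists lay below those of all 10000 random lists of the same size and signal, and that of the recombination list at percentile 0.16. Among 5 measured inhibitors of cyclin-dependent kinases the median was 1.84. CDKN1A, CDKN1C (5.07-fold) and CDKN2D (3.57-fold) rose, and CDKN1B fell, 2.33-fold lower.

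Of 11 histone genes, 8 rose and 1 fell, with a median of 1.23 at percentile 99.99; H2BC21 rose 7.5-fold and H2BC5 4.32-fold. The list of known histone deacetylase inhibitor response genes had a median of 0.93 at percentile 99.98, and 6 of its 12 measured members rose, among them TXNIP at 8.19-fold. Antigen presentation genes had a median of 1.07, with 8 of 15 rising and 2 falling; the largest folds were those of HLA-DMB (12.7-fold) and HLA-DPA1 (10.4-fold). When probe sets that can match several transcripts were left out, 9 of these genes were measured and the median was 0.73, at percentile 97.08, just inside the central range. Of 27 listed neuronal genes 14 were measured, and of these 8 rose and 0 fell, with a median of 1.14 at percentile 99.93. The secretory granule gene SCG2 rose at least 12.5-fold. Of 19 listed cancer-testis genes, which are normally silent outside the germ line, 7 were measured and 4 rose. The measured genes had a median of 1.01 at percentile 99.29, and SSX1 rose at least 15.0-fold. Members of either list below the floor in untreated cells were measured only if they rose above it, so they could not count as falls. The cancer-testis call was lost under both other floors.

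Genes of cholesterol synthesis were also higher, with 8 of 19 rising, a median of 0.72 above all random lists, and HMGCS1, the synthase that precedes the rate-limiting step, 5.97-fold higher. Of 26 lysosome and autophagy genes 10 rose and 0 fell, with a median of 0.43 at percentile 99.72; the sialidase NEU1 rose at least 13.7-fold and GABARAPL1 4.44-fold. Anti-apoptotic genes were lower, with a median of -0.93 at percentile 0.20. In that list, BCL2A1 was 7.87-fold lower, CFLAR 3.71-fold lower and BCL2L1 2.73-fold lower. The list of MYC and ribosome biogenesis genes had a median of -0.49 at percentile 0.92, and 4 of 16 fell, MYC itself 3.12-fold lower. Metallothioneins had a median of -0.46 at percentile 1.28 with 1 fall in 7, MT1G at 2.49-fold lower, and genes of MAP kinase output a median of -0.42 at percentile 1.79. In the last list members went both ways, with FOSL1 lower and EGR1 14.5-fold and DUSP6 8.30-fold higher. The metallothionein call was kept under 6 of 8 alternative settings and the MAP kinase call under 6 of 9.

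Of the 34 lists with at least 5 measured members, 15 lay outside the central 95% of random lists, where chance gives about 1 in 20. Of the histone deacetylase genes 11 were measured, and 3 rose and 1 fell, with a median of 0.16 at percentile 70.21. HDAC1 was at 12525 in untreated cells and 14306 with romidepsin, HDAC2 at 8965 and 10051, and HDAC3 rose from 1685 to 3645, while HDAC7 was 3.65-fold lower. Of 1159 called genes with a second probe set, both above the floor on both arrays, that probe set moved the same way in 1101. In 59.0% it also changed at least 2-fold. Both probe sets read the same RNA on the same arrays, so this does not replicate a call.

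Tamoxifen alone was compared with no treatment, and its main feature was a rise of cholesterol synthesis genes. Of 19 measured, 10 rose and 0 fell, with a median log2 fold of 1.22 above all 10000 random lists. HMGCS1 rose from 717 to 3931, 5.48-fold, IDI1, the isomerase of isoprenoid synthesis, 5.28-fold, the sterol desaturase SC5D 4.6-fold and the sterol carrier STARD4 4.05-fold. Mitosis genes did not share the fall seen with romidepsin: 0 of 29 rose or fell, and the median was -0.18 at percentile 10.63. FOXM1 was at 1568 against 2353 in untreated cells. In all, 483 genes rose and 140 fell among 13051 measured.

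The direction of these calls depended on how the arrays were scaled. Rises made up 77.5% of the calls as deposited, 48.0% with arrays centred on their medians (293 higher, 317 lower), 63.4% after quantile normalization (353 and 204) and 98.3% when scaled to the spike-in controls (1526 and 27).

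Of the other largest rises measured on both arrays, the transmembrane glycoprotein GPNMB rose 4.44-fold, DOCK11 4.23-fold, the nicotinic receptor subunit CHRNB2 3.99-fold and KBTBD3 3.96-fold. TP53INP1, a p53 target, rose at least 5.40-fold from the floor, CREBRF at least 3.79-fold and C2CD2L at least 3.65-fold. The largest falls were those of the noncoding RNA VESTAR, 3.49-fold lower, the transporter SLC6A17, 3.41-fold lower, and the growth factor binding protein IGFBP3, 3.05-fold lower. The endothelin precursor EDN1 was 3.02-fold lower, NPM2 and ESAM were each 2.98-fold lower, COQ8B was 2.72-fold lower and GRWD1 2.62-fold lower. ARHGEF17 and PYCR3 were each at least 4.03-fold lower, and XYLB at least 3.43-fold lower. VESTAR was lower with tamoxifen alone, but its log2 fold in the combination over romidepsin was only -0.06.

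Genes of fatty acid synthesis had a median of 0.38 at percentile 99.50 with tamoxifen, and 2 of 14 rose, ACSS2 at 3.20-fold and ELOVL6 at 3.05-fold. DNA replication genes had a median of -0.46 at percentile 0.01, with 2 of 29 falling, the licensing factor CDT1 at 2.26-fold lower and MCM2 at 2.10-fold lower. MYC and ribosome biogenesis genes had a median of -0.47 at percentile 0.05, with 0 of 16 rising or falling. Both calls held under all 9 alternatives, but the sizes varied. The replication median lay between -0.61 and -0.11 and the MYC median between -0.62 and -0.11. The histone deacetylase inhibitor response list had a median of 0.25 at percentile 98.13, but that call held under only 3 of 9 alternative settings and 1 of 12 members rose. These 5 of 35 lists lay outside the central range. The cystine transporter SLC7A11 rose from 493 to 1328, 2.70-fold, the phospholipid-remodelling enzyme ACSL4 rose 2.09-fold, and the stress-response transcription factor DDIT3 rose 2.72-fold.

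**Figure D1:**
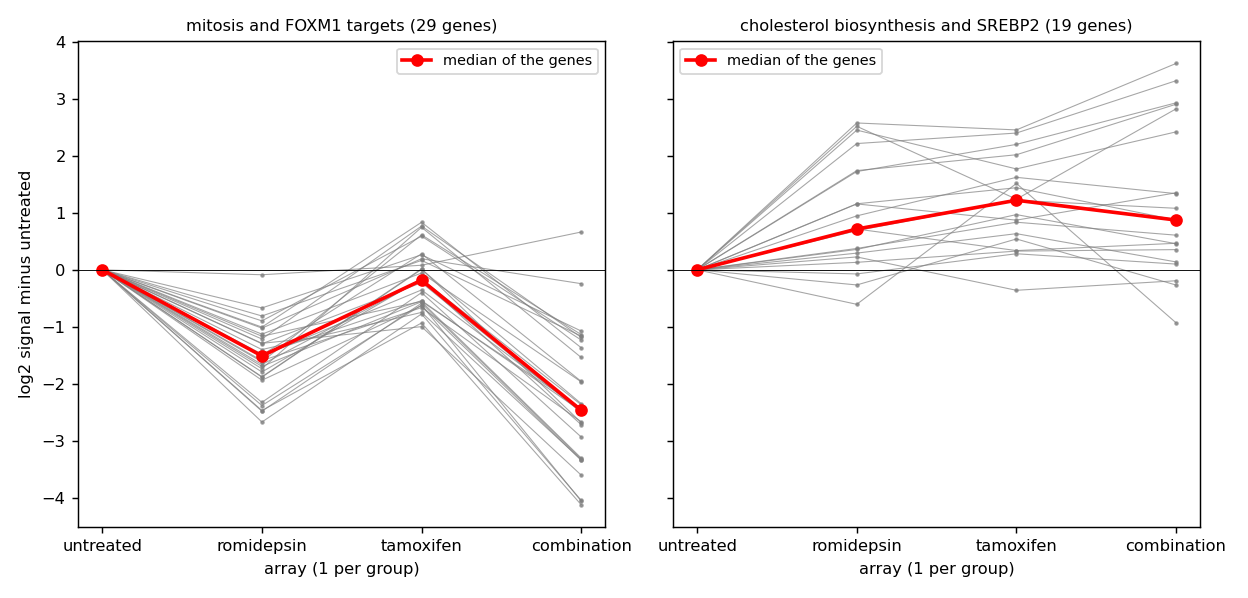
Log2 signal minus the untreated array (vertical axis) on each of the 4 arrays for the 29 measured mitosis genes and FOXM1 targets (left) and the 19 cholesterol synthesis genes (right). Each gray line is a gene and the red line is the median over genes, which lies at -1.51, -0.18 and -2.46 on the left and 0.72, 1.22 and 0.87 on the right for romidepsin, tamoxifen and the combination.

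The combination was compared with no treatment. The mitosis genes were lower than with either drug alone, and cholesterol synthesis genes were higher than in untreated cells. Of 29 mitosis genes 27 fell and 0 rose, with a median log2 fold of -2.46, below all random lists. The mitotic kinases PLK1 and AURKB were 17.4-fold and 16.7-fold lower, the ubiquitin-conjugating enzyme UBE2C 16.5-fold lower, CDC20 12.2-fold lower, and FOXM1 9.99-fold lower, at 236. HMGCS1 rose 12.3-fold and IDI1 9.98-fold. In all, 2727 genes rose and 1984 fell among 13802 measured, 57.9% rises; the share was 41.2% with arrays centred on their medians (2026 and 2886) and 72.8% when scaled to the spike-in controls.

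DHRS2 rose 72.5-fold, the neuronal protease inhibitor SERPINI1 53.7-fold, ABAT 49.0-fold, DNER 42.8-fold, PRKAR2B 40.4-fold, GPR160 38.1-fold, GATM 32.7-fold and the kinesin KIF5C 30.4-fold. CYP4F2, a cytochrome P450, rose at least 74.4-fold from the floor, SESN3 at least 66.9-fold and the glucose transporter SLC2A3 at least 59.4-fold. PLAU was 67.0-fold lower, MYOF 32.5-fold lower, FOSL1 31.6-fold lower, PLAC8 19.9-fold lower, RIN2 19-fold lower, NUPR1 18.2-fold lower and MALL 17.0-fold lower. The collagen chaperone SERPINH1 was at least 23.7-fold lower, PRRX2 at least 12-fold lower and ANK1 at least 11.4-fold lower.

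DNA replication genes had a median of -1.68 with 21 of 29 falling, and recombination genes a median of -1.13 with 7 of 14 falling. Histone genes had a median of 1.54 with 7 of 11 rising, inhibitors of cyclin-dependent kinases a median of 1.68, neuronal genes 1.37, antigen presentation genes 0.77 and lysosome genes 0.47. Cholesterol synthesis genes had a median of 0.87 with 9 of 19 rising, against a median of 1.22 with tamoxifen alone. Epithelial markers had a median of -0.85 at percentile 0.05. Members of that list went both ways: 8 of 16 fell, CLDN4 at 9.15-fold lower, and 4 rose, with DSP at least 27.2-fold and EPCAM at least 7.15-fold higher. Glycolysis and hypoxia genes had a median of 0.62 at percentile 99.76 with 7 of 22 rising and 4 falling. MYC and ribosome biogenesis genes had a median of -0.74 with MYC 8.03-fold lower. Of 34 lists, 13 lay outside the central range. Leaving out probe sets that can match several transcripts, which left fewer members, ended calls of 5 lists. The medians were then -0.22 for epithelial markers, 0.73 for antigen presentation, 0.52 for glycolysis, -0.56 for MYC and ribosome biogenesis and 0.56 for histone deacetylase inhibitor response, which had a median of 0.68 before. Taking the median over the probe sets of a gene also ended the glycolysis and MYC calls. The floor at the 75th percentile ended the call of the cyclin-dependent kinase inhibitors, and random lists not matched on signal ended those of the lysosome and histone deacetylase inhibitor response lists.

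**Figure D2:**
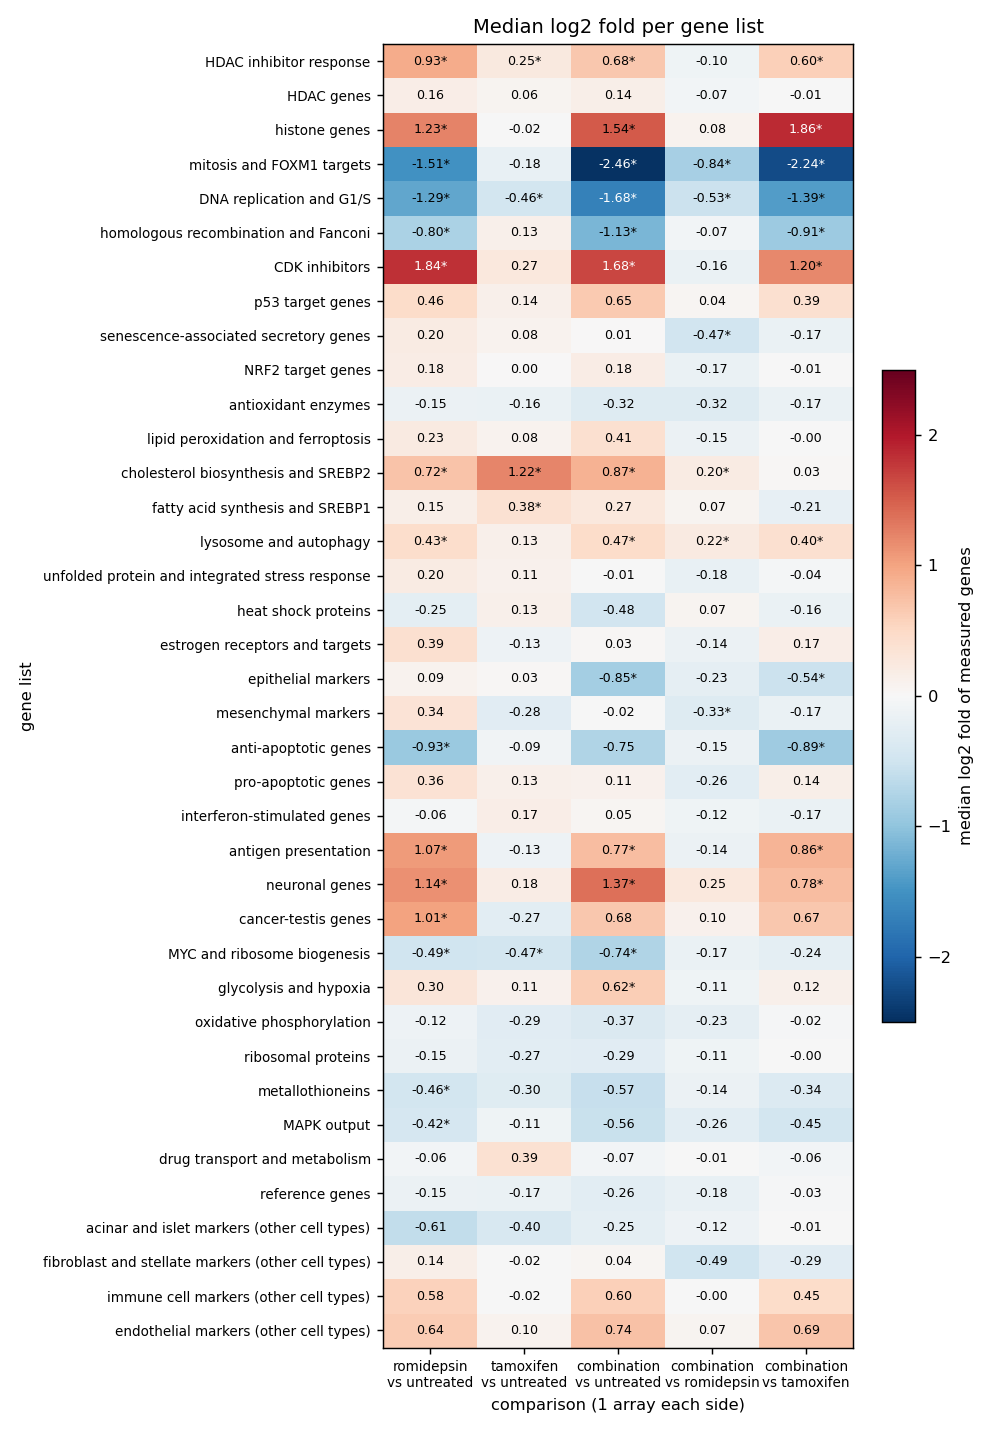
Median log2 fold (color, with the value in each cell) of each of the 38 gene lists (rows) in each of the 5 comparisons (columns), 1 array on each side; an asterisk marks medians outside the central 95% of 10000 random lists matched on signal. The mitosis list reaches -2.46 in the combination against untreated cells, and cholesterol synthesis genes reach 1.22 with tamoxifen alone.

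Tamoxifen added to romidepsin was examined by comparing the combination with romidepsin alone. Mitosis genes were lower again, and so were genes of the senescence-associated secretory list. Of 29 mitosis genes 12 fell and 0 rose, with a median log2 fold of -0.84 below all random lists. CDC20, an activator of the anaphase-promoting complex, went from 5297 to 1066, 4.97-fold lower, the survivin gene BIRC5 was 3.82-fold lower and AURKB 3.20-fold lower. FOXM1 was at 421 with romidepsin and 236 with the combination, and CDKN1A at 7755 and 7644. In all, 559 genes rose and 312 fell among 13726 measured, 64.2% rises; the share was 46.4% with arrays centred on their medians and 93.7% when scaled to the spike-in controls.

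Of 23 measured genes of the senescence-associated secretory list, 8 fell and 1 rose, with a median of -0.47 below all random lists, a call lost with the lower floor. CXCL1 went from 1592 with romidepsin to 246 with the combination, 6.47-fold lower, CCL20 from 1972 to 427, 4.61-fold lower, and CXCL8 and CXCL2 were 3.88-fold and 3.40-fold lower. In untreated cells CXCL1 was at 98.0 and CCL20 below the floor. With romidepsin alone, 9 members of this list rose and 7 fell, and its median was 0.20 at percentile 75.27. NES, which encodes nestin, was 5.35-fold lower in the combination than with romidepsin, PTX3 4.49-fold lower and KRTAP3-1 4.25-fold lower. The largest rises were those of DNAI7 (4.53-fold), TTC14 (4.37-fold), TENM1 (4.05-fold), the mitochondrial carrier SLC25A27 (3.84-fold), the splicing kinase CLK1 (3.80-fold) and CXCL11 (3.77-fold).

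DNA replication genes had a median of -0.53, with 5 of 29 falling and CCNE2 rising 2.39-fold. Cholesterol synthesis genes had a median of 0.20 at percentile 99.68, and 4 of 19 rose, namely SC5D, STARD4, IDI1 and HMGCS1, at between 2.06-fold and 2.31-fold. The cholesterol call was lost against random lists not matched on signal. Lysosome genes had a median of 0.22 at percentile 99.78 with 0 of 27 rising or falling. Mesenchymal markers had a median of -0.33 at percentile 1.62 with 3 of 18 falling, AXL at 2.31-fold lower. This call held under 7 of 9 alternative settings, over which the median lay between -0.44 and -0.02. NQO1, an enzyme of the NRF2 response, was at 6938 in untreated cells, 4121 with romidepsin, 7251 with tamoxifen and 1830 with both, and fell by 1.17 on the log2 scale between romidepsin alone and the combination. Of 35 lists, 6 lay outside the central range.

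Romidepsin added to tamoxifen was examined by comparing the combination with tamoxifen alone. The picture resembled that of romidepsin against untreated cells: 27 of 29 mitosis genes fell, with a median of -2.24, and 7 of 11 histone genes rose, with a median of 1.86. DHRS2 rose 49.8-fold, SESN3 47.0-fold, PRKAR2B, which was next to the floor with tamoxifen, at least 41.3-fold, GATM 25.9-fold, DNER 23.6-fold and GPR160 23.4-fold. PLAU was 61.9-fold lower, NUPR1 36.0-fold lower, MYOF 29.3-fold lower, the coagulation inhibitor TFPI 27.9-fold lower, the guidance genes NTN4 and NRP1 23.2-fold and 20.1-fold lower. In all, 2051 genes rose and 1644 fell among 13893 measured, 55.5% rises; with arrays centred on their medians 1690 rose and 2002 fell, 45.8% rises. The cholesterol list had a median of 0.03 at percentile 65.71, although INSIG1 (3.0-fold) and HMGCS1 (2.24-fold) rose and ACAT2 was 5.45-fold lower.

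Of 35 lists, 11 lay outside the central range in this comparison. Besides mitosis and histone genes these were DNA replication (-1.39), recombination (-0.91), inhibitors of cyclin-dependent kinases (1.2), histone deacetylase inhibitor response (0.60), antigen presentation (0.86), neuronal genes (0.78), lysosome genes (0.40), anti-apoptotic genes (-0.89) and epithelial markers (-0.54). Leaving out probe sets that can match several transcripts ended the calls of the epithelial (median then -0.08), antigen presentation (0.63) and histone deacetylase inhibitor response (0.21) lists. Random lists not matched on signal ended those of the lysosome and histone deacetylase inhibitor response lists, and the floor at the 75th percentile that of the epithelial list.

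The effect of each drug could be compared between arrays that share no sample. Across 13098 genes, the log2 folds of romidepsin against untreated cells and of the combination against tamoxifen had a Pearson correlation of 0.90 and a Spearman correlation of 0.87. Of 1947 genes that rose in the first comparison 1488 rose in the second, where independent lists would share 302, and of 1255 that fell 1009 fell again, where independent lists would share 157. For tamoxifen, in the comparisons with untreated cells and with romidepsin, the Pearson and Spearman correlations were both 0.61 across 12363 genes, and the Pearson correlation was 0.32 with the floor at the 25th percentile and 0.74 at the 75th. Of 477 genes that rose 164 rose again against 18.4 for independent lists, and of 135 that fell 24 fell again against 3.23. Genes are not independent replicates. The tamoxifen and combination arrays also differed from the other pair in their hybridization controls and in their labelling controls other than thr, which were at 0.656 and 0.697 times the untreated level against 0.988 times with romidepsin.

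**Figure D3:**
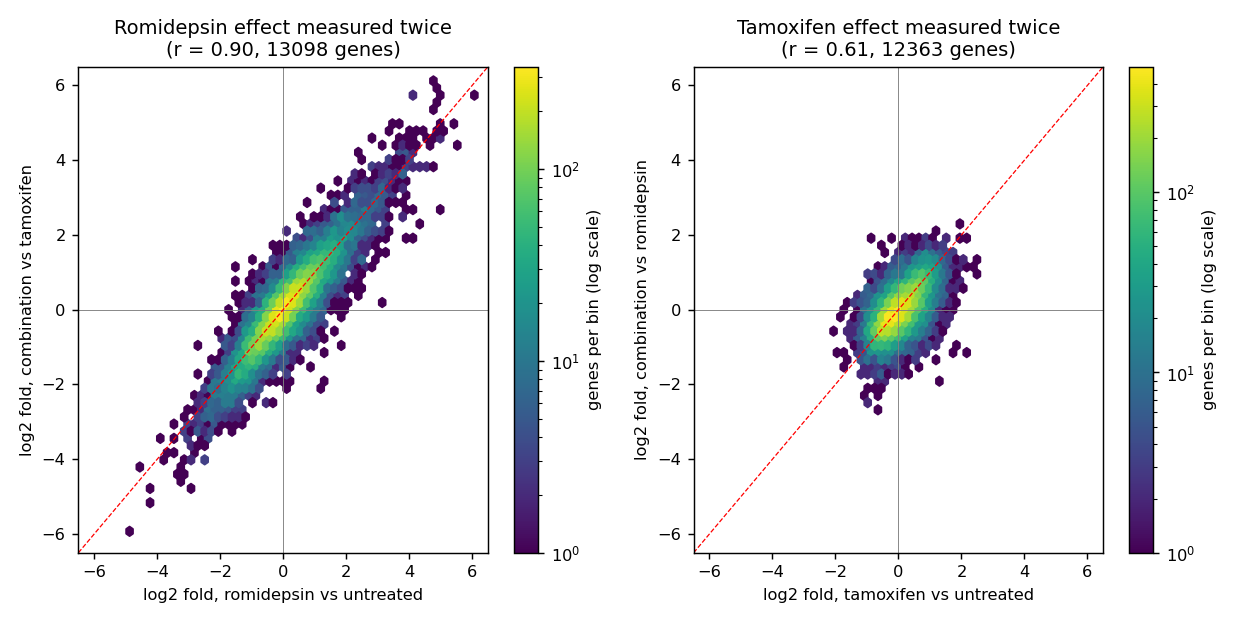
Log2 fold of each gene for romidepsin (left; romidepsin over untreated cells against combination over tamoxifen) and tamoxifen (right; tamoxifen over untreated cells against combination over romidepsin), with color giving the number of genes per bin on a log scale and the dashed line marking equal folds. The folds correlate at r = 0.90 on the left, where they spread more widely, and at r = 0.61 on the right; the distance of a gene from the line is the same departure from additive effects in both panels.

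Genes set apart on the combination array, at least 2-fold beyond all 3 other arrays, were counted to see what both drugs gave together. There were 256 such genes on the high side and 181 on the low side, against 50 and 180 for the untreated array, 35 and 22 for romidepsin and 53 and 23 for tamoxifen. With the floor at the 25th percentile the combination array had 446 and 320 and the untreated array 172 and 530. With the floor at the 75th percentile they had 123 and 85, and 26 and 59. With arrays centred on their medians, genes set apart higher on the combination array numbered 164 and genes set apart lower on the combination array 278; scaled to the spike-in controls they numbered 497 and 57. The other arrays moved too: median-centring gave 119 and 108 for the untreated array, 36 and 24 for romidepsin and 37 and 44 for tamoxifen, and spike-in scaling 7 and 392, 15 and 55, and 223 and 8. Of those low on the combination array with all 4 arrays above the floor, CDC20 was 4.97-fold below the nearest array, BIRC5 3.82-fold, the kinetochore gene SPC24 3.47-fold and CDCA3 3.44-fold, together with the cytidine deaminase APOBEC3B at 4.23-fold and PLAC8 at 3.61-fold. The largest margins on the high side were those of the chaperone CLGN, 3.72-fold above the nearest array, ERGIC2 (3.45-fold), SERPINI1 (3.30-fold), ZNF594 (3.09-fold), the ciliary gene CEP290 (3.07-fold) and CIRSR (3.0-fold).

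Relative to the sum of both single-drug effects on the log2 scale, 273 of 14414 genes were at least 2-fold above and 376 at least 2-fold below. Both counts depended strongly on the floor, being higher with the lower floor and lower with the higher one. Mitosis genes had a median departure of -0.72, below all random lists, with 5 of 29 at least 2-fold below the sum. Cholesterol synthesis genes had a median departure of -0.85, also below all random lists, with 6 of 19 at least 2-fold below. HMGCS1 was thus at its highest with both drugs but 1.41 lower on the log2 scale than the sum. Of the secretory list 6 of 24 genes were at least 2-fold below the sum and 1 at least 2-fold above. Medians below the central range were also those of pro-apoptotic, drug transport, fatty acid synthesis, MAP kinase output, cyclin-dependent kinase inhibitor and epithelial lists. On the other side lay MYC and ribosome biogenesis genes, with a median departure of 0.31 at percentile 99.99, and ribosomal proteins, with 0.15. Both single-drug effects use the same untreated array, so an error on that array enters every departure. The list departures were not run under the alternatives.

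Lists fixed for oxidative stress and for tamoxifen's known receptor lay within the central range in each comparison. With the combination against untreated cells, NRF2 targets had a median of 0.18, antioxidant enzymes -0.32, lipid peroxidation and ferroptosis genes 0.41, unfolded protein and integrated stress response genes -0.01, heat shock proteins -0.48 and p53 targets 0.65. The p53 list was close to the limit, at percentile 97.15, and gained a call under 3 of 9 alternative settings there and under 3 of 9 for romidepsin alone. Some other lists of this group gained a call in a comparison under 1 or 2 alternatives: unfolded protein and stress response, lipid peroxidation, heat shock, antioxidant enzyme and estrogen receptor lists. Of 20 measured NRF2 targets 4 rose and 3 fell: the aldo-keto reductases AKR1C1, AKR1C2 and AKR1C3 rose 6.85-fold, at least 7.94-fold and at least 9.63-fold, while ABCC3 was 8.53-fold lower and NQO1 3.79-fold lower. Of 19 measured lipid peroxidation and ferroptosis genes 7 rose and 4 fell, and the ferroptosis suppressor AIFM2 was 7.35-fold lower. The signal of HMOX1 was at 555, 520, 629 and 815 on the untreated, romidepsin, tamoxifen and combination arrays, and that of GPX4, which reduces lipid hydroperoxides, at 18203, 23739, 13893 and 15279. The estrogen receptor list had a median of 0.03 in the same comparison. The ESR1 probe set used here was below the floor without romidepsin, at 33.3 in untreated cells and 48.1 with tamoxifen, and at 122 with romidepsin and 197 with the combination. The probe sets of ESR1 did not share a direction: of 4 measured for romidepsin against untreated cells, 1 was higher and 3 were lower. The drug efflux pump ABCB1 rose at least 5.17-fold with romidepsin and at least 8.58-fold with the combination, while its list of drug transport and metabolism genes had a median of -0.07.

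In the combination against untreated cells, pro-apoptotic genes had a median of 0.11, interferon-stimulated genes 0.05, oxidative phosphorylation genes -0.37, ribosomal proteins -0.29 and common reference genes -0.26. None of these 5 lists lay outside the central range in any of the 5 comparisons, although pro-apoptotic, oxidative phosphorylation and ribosomal protein genes each gained a call in 1 comparison under an alternative. Markers of other cell types were mostly below the floor. In this comparison 3 of 16 acinar and islet markers, 4 of 12 fibroblast markers, 4 of 14 immune markers and 4 of 8 endothelial markers were measured, too few for a percentile. The median log2 folds were -0.25, 0.04, 0.60 and 0.74 in that order.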

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

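The tests of a processing batch and of a low reading of the untreated array were chosen after the results were seen.

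The effect of a drug without the other drug was set beside its effect in the presence of the other. Lists are given here where the medians had opposite signs and at least 1 lay outside the central range, and named genes where the folds had opposite signs, 1 of them at least 2-fold and the other at least 1.5-fold; other lists and genes had opposite signs but did not meet these limits. For each of them the difference was not tested, since each effect rests on a single pair of arrays. The histone deacetylase inhibitor response list had a median log2 fold of 0.25 with tamoxifen alone and -0.10 with tamoxifen added to romidepsin. The secretory list went from 0.08 to -0.47 in the same comparisons. Epithelial markers had a median of 0.09 with romidepsin alone and -0.54 with romidepsin added to tamoxifen. The noncoding RNA VESTAR had a log2 fold of -1.03 with romidepsin alone and 0.72 with romidepsin added to tamoxifen. TFPI had a log2 fold of 0.89 with tamoxifen alone and -1.07 with tamoxifen added to romidepsin. A signal also appeared outside the genes of the cells: the thr spike-in control, added as RNA during labelling, was 1.75-fold higher on the romidepsin array than on the untreated array, while the other labelling controls were at 0.988 times. On the tamoxifen array thr was at 0.987 times and the others at 0.656 times, and on the combination array at 1.2 and 0.697 times, so thr was high relative to the others on all 3 treated arrays. That difference was not tested either.

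The folds of tamoxifen alone and of tamoxifen added to romidepsin correlated across genes. After trends with gene length and chromosome were removed, the correlation was 0.57, which argues against those trends as the whole cause. Hybridization spike-in controls were lower by a log2 difference of -0.33 on the arrays with tamoxifen than on the others. This split is also the treatment, so a processing batch and tamoxifen cannot be told apart for this correlation as a whole. An effect of the drug stays open.

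Cholesterol synthesis genes were higher in each treated sample than in the untreated one. A low reading of the untreated array alone would leave no difference between the combination and romidepsin. The list lay at percentile 99.68 there, which argues against such a reading as the whole cause for tamoxifen. That call was lost against random lists not matched on signal. The median there was only 0.20, with 4 of 19 genes rising, against 1.22 and 10 of 19 for tamoxifen alone. A low untreated array could still have given much of the larger value. For romidepsin the matching comparison, combination over tamoxifen, gave percentile 65.7, with members going both ways, so a low untreated array and an effect of romidepsin that tamoxifen masks cannot be told apart. The departure of these genes from the sum of both effects lay at percentile 0 among lists of equal brightness. Those lists were not matched on how far genes rose, so this cannot decide whether compression of bright signals gave it. A low untreated array would also give a departure below 0. A shared route of both drugs to the same genes may explain it and was not tested.

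Mitosis genes were lower in the combination than with romidepsin alone. The highest median under the 3 other scalings was -0.53, and the median after removal of trends with gene length and chromosome was -0.82, so neither explains the whole fall. More 3′ bias on the combination array could lower part of the probe sets: 85.1% of the measured ones, 40 of 47, were lower, which leaves this open. An added effect of tamoxifen on dividing cells stays open too. The combination and romidepsin arrays also lie on opposite sides of the split in spike-in controls, so a processing batch was not separated from tamoxifen here. Tamoxifen over untreated cells crosses the same split, and the mitosis median there was -0.18, with 0 of 29 genes falling.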

How the results depend on the processing

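The spike-in scaling and the removal of trends were added after the data were seen. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array. Of 175 values that answer a comparison, 131 stayed within a margin set for counts or correlations and 44 moved. Of 1531 list medians 1453 kept their call or lack of one, 44 gained a call, 33 lost one and 1 reversed. These include the medians that had no call. Calls kept under all alternatives run numbered 11 of 15 for romidepsin, 4 of 5 for tamoxifen and 6 of 13 for the combination. They numbered 3 of 6 for the combination over romidepsin and 7 of 11 for the combination over tamoxifen. An uncalled median could change sign and still count as kept. Of 1351 folds of named genes 1308 stayed on the same side of the 2-fold limit, though their size could shift. Many of these genes were named for their large folds, which seldom come near that limit. This share therefore does not carry over to other called genes. Of 42 counts of genes set apart on the other arrays 24 moved and 18 did not. The mitosis list kept its call under all alternatives run in each of the 4 comparisons that had one. Higher and lower counts follow in that order. With the floor at the 25th percentile, more dim genes can be called: romidepsin 3018 and 1901, tamoxifen 1471 and 749, combination over romidepsin 1254 and 828, combination over tamoxifen 3079 higher, genes set apart higher on the combination array 446, genes set apart lower on the combination array 320, genes above additive effects 1317, genes below additive effects 1609, and correlations of 0.77 for romidepsin and 0.32 for tamoxifen. With the floor at the 75th percentile, fewer genes can be called: 800 and 832, 195 and 58, combination over untreated 1423 higher, over romidepsin 266 and 131, over tamoxifen 971 and 1043, set apart 123 and 85, beyond additive effects 74 and 76, and a tamoxifen correlation of 0.74. Under that floor the cancer-testis median for romidepsin reversed to -0.10; the cause was not tested. Median-centring gave 293 and 317 for tamoxifen and 164 and 278 set apart; it moved the median of all genes by -0.17 for romidepsin, -0.14 for tamoxifen and -0.26 for the combination, and by -0.10 over romidepsin and -0.13 over tamoxifen; quantile normalization moved that of the combination by -0.10. Spike-in scaling gave 1526 and 27 for tamoxifen, 1324 and 89 for the combination over romidepsin and 497 and 57 set apart, and moved the median by 0.32, 0.29 and, for the combination over untreated cells, 0.25. Adding 16 in place of a floor gave 1459 and 717 for tamoxifen. The median over probe sets gave 151 genes above additive effects. Without probe sets that can match several transcripts 118 genes were set apart lower, and 7 lists lay outside the central range for the combination over untreated cells and 7 over tamoxifen, of fewer genes measured. Removal of trends gave 9 lists for tamoxifen. For scalings, probe-set choices and trends the cause was not tested. Signal over background limits the dim genes, where the choice of floor decides the call.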

Other observations

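The test of dim and bright genes was planned before its result was seen, and the gene families below were picked after their values were seen.

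Genes named by a shared stem, with at least 12 measured members, showed groups that no list covered. Intraflagellar transport genes (IFT), which build the cilium, had a median log2 fold of 0.98 with romidepsin, with 8 of 18 rising, and 1.11 with romidepsin added to tamoxifen, with 10 of 18 rising. Centrosomal protein genes (CEP) had a median of 0.47 with tamoxifen, with 5 of 35 rising, and 0.71 with tamoxifen added to romidepsin, with 13 of 36 rising, the highest of 127 families. With romidepsin added to tamoxifen the CEP median was 0.43 at percentile 98.03, with 10 of 36 rising and 3 falling. With romidepsin alone it was 0.19 at percentile 80.21. Zinc finger genes (ZNF) had a median of 0.29 with tamoxifen added to romidepsin, with 51 of 373 rising and 2 falling. These medians stayed above 0 under the 3 other scalings, which do not remove trends with gene length and chromosome.

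Mitochondrial ribosomal protein genes were lower with romidepsin. The large subunit genes (MRPL) had a median of -0.40, with 7 of 49 falling, and the small subunit genes (MRPS) a median of -0.44, with 2 of 27 falling. With romidepsin added to tamoxifen the medians were -0.30, with 7 of 49 falling and 1 rising, and -0.31, with 1 of 27 falling, the latter within the central range at percentile 5.23. With tamoxifen alone the medians of -0.34 and -0.26 turned to 0.01 and 0.10 under spike-in scaling, so their direction there depends on the scaling. Annexin genes (ANXA), which bind membranes, had a median of -0.38 with romidepsin alone, with 1 of 14 falling. That lay just inside the central range, at percentile 2.62. With romidepsin added to tamoxifen the annexin median was -0.83, with 6 of 14 falling.

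Tamoxifen folds followed gene length, with a Spearman correlation of 0.26 for tamoxifen alone and 0.22 for tamoxifen added to romidepsin, against 0.06 and 0.04 for romidepsin. They differed by chromosome too. On chromosomes 19, 22, 4 and 13 the medians were -0.22, -0.22, 0.24 and 0.27 with tamoxifen alone. With tamoxifen added to romidepsin they were -0.24, -0.23, 0.17 and 0.18, and with romidepsin alone 0.02, -0.03, 0.25 and 0.18. The arrays with tamoxifen also differed in their spike-in controls, so the drug and a processing batch cannot be told apart here.

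Dim genes rose more often than bright genes in the romidepsin comparisons. With brightness taken from an array that the fold does not use, the share of genes that rose was at least 5.64 times as high in the dimmest of 5 equal bins as in the brightest in each of the romidepsin comparisons. The tamoxifen comparisons had this pattern too, with 3.95% against 1.26% for tamoxifen alone and 6.46% against 0.434% for tamoxifen added to romidepsin. The pattern is thus not specific to romidepsin, and its cause was not tested.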
